A study of Homo sapiens with 9 samples.

How the data were processed

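RNA was sequenced from 9 libraries of THP-1 cells that had been turned into dendritic cells: 3 with PFOA, 3 with PFOS and 3 with the DMSO vehicle. The labels' protocols give on-column DNase treatment, poly(A) selection and the NEBNext Ultra library kit. Per the submitters' processing notes, cutadapt 1.16, HISAT2 2.2.1, SAMtools 1.9, HTSeq 0.11.2, limma 3.50.3 and edgeR 3.36.0 were used with the build GRCh38.p13, and no parameters or annotation release are recorded. The values the authors deposited are a normalised signal per gene and library, named normalised counts in the file's title, with 1 column for each library. The method of that normalisation is not recorded. The strand setting of the gene counting is not recorded either, so values of genes that overlap each other or an antisense gene are uncertain, as are those of near-identical copies such as HLA and metallothionein genes.

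Each deposited column was found to hold whole multiples of its smallest positive value, within 0.001 for 100% of values, which gives back whole reads, counted here in M (mega). The recovered totals were 74.6, 86.8 and 67.5 M reads in the control libraries, 56.1, 67.4 and 51.9 M in the PFOA libraries and 71.6, 33.2 and 77.6 M in the PFOS libraries. The factors between these reads and the deposited values equalled the median-of-ratios size factors of DESeq2, with a largest difference of 1.22e-15. The normalised totals ran from 60.2 to 64.0 M. A single read stood for 0.0115 to 0.0304 CPM. A floor of 3 reads stood for 0.0346 to 0.0913 CPM and was not applied as a filter. These limits cover counting error only.

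Values were divided by the mean column total of 62.8 M to give normalised counts per M, called CPM here, and log2 was taken after adding 1 CPM. Genes with at least 1 CPM in at least 3 of the 9 libraries were tested, which kept 13932 of 60605 genes and at least 99.7% of the reads of each library. The file gives gene IDs, and a reference table of gene names matched 60463 of the 60605 IDs. 609 tested genes had no symbol and were used by ID. Positions came from GENCODE release 29 on GRCh38, which holds 13869 of the tested genes and may differ from the release the submitters used. A linear model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level. PFOA against control, PFOS against control and PFOS against PFOA were tested as contrasts of that fit, two-sided, with Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05, with no fold threshold. The plan named edgeR in case of whole counts. Because the deposited unit was a normalised signal, limma was kept, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives.

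The design, the tests, 27 gene lists, 6 lists of cell type markers and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 10 largest rises and the 10 largest falls among called genes with a symbol whose groups did not overlap and whose higher group reached 5 CPM, up to 4 members of each list with the smallest p, and 20 genes whatever their values. Genes outside the rule are named as such where they appear. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. At least 3 measured members were required, a minimum set after the first list output had been seen, which left 30 of the 33 lists tested. For these fixed lists, gene counts are also given as adjusted over the list alone.

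The fit was tested on simulated data for PFOA against control, with reads drawn for 13840 genes at the real means and depths. It recovered 61.2% of genes changed 1.5-fold, 90.6% of those changed 2-fold and 100% of those changed 4-fold. Of the calls, 4.62% were unchanged genes. In the PFOS against control comparison, where nothing had been changed, limma called 0 genes. In the simulated PFOA against control comparison camera called the shifted list. Genes were drawn independently there, so the simulation says nothing about false list calls where the genes of a list are correlated.

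The alternatives fixed beforehand were other pseudocounts, no filter and a stricter filter, quantile normalisation, median centring, a replicate block, variances without a trend, array weights, a fit on the 6 libraries compared, a fold threshold and leaving out each library in turn. Alternatives chosen after seeing the data were edgeR, DESeq2, reads thinned to the smallest library, a correction for GC content and length, and the testing of lists with 1 or 2 members. Chance overlap between the compounds was simulated 100 times with the same control libraries. A replicate block in the control and PFOS libraries alone was also added. The labels do not say that a replicate number marks a shared culture or day. In the data, libraries of the same number deviated together between control and PFOS, with all 3 correlations over 0.1 (0.138 to 0.309). Control 3 and PFOS 2, of different numbers, had 0.204, so these values do not settle whether the numbers pair these groups. Libraries of the same number did not deviate together between control and PFOA (-0.282 to -0.158) or between PFOA and PFOS (-0.524 to -0.0416). No library was left out of the reported values.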

Results

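The data were 9 poly(A)-selected RNA-seq libraries from THP-1 cells, an established human monocytic leukaemia line. The cells had been differentiated for 5 days with IL-4 and GM-CSF into immature dendritic cells. They then received PFOA at 10 µg/mL (24.4 µM), PFOS at 10 µg/mL (20 µM) or the solvent DMSO at 0.1%. After 24 h a cocktail of IL-4, GM-CSF, TNF-α and ionomycin was added for another 24 h to mature the cells, with the compounds still present, so that exposure lasted 48 h. Each group had 3 libraries, called by group and replicate number here. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples only. Recovered reads ran from 33.2 M in PFOS 2 to 86.8 M in control 2, and 25062 to 28061 genes had a value above 0. Levels below are normalised CPM (counts per M of the mean library total), as mean ± SD with n = 3. Log2 fold changes, their order and the 2-fold counts were taken after adding 1 CPM. This makes the changes of genes at low levels smaller than the ratios of their mean CPM.

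PFOS 1 and PFOS 2 lay farther from their group mean than the other libraries. The root mean square deviation over genes was 0.205 log2 units in PFOS 1 and 0.173 in PFOS 2, against 0.0717 to 0.123 in the 7 other libraries. The first principal component held 48.4% of the variance and placed the control libraries at -16.4 to -7.46 and the PFOA libraries at 7.02 to 20.9. It placed PFOS 1 at -20.5, PFOS 2 at 12.8 and PFOS 3 at 2.16. The second held 20.8% and placed the control libraries at 6.49 to 8.42 and the PFOA libraries at -11.5 to -1.79. On it PFOS 1 lay at -14.6, PFOS 2 at 10.6 and PFOS 3 at 3.91. Chi-square per gene between PFOS 1 and the control libraries was 48.8 to 56.0, against 12.1 to 27.3 among the controls, and it was 83.8 and 71.8 between PFOS 1 and PFOS 2 and 3. PFOS 2 lay at 21.9 to 30.7 from the PFOA libraries, which lay at 15.8 to 30.9 from each other, and at 19.7 from PFOS 3. This chi-square was taken on recovered reads and rises with depth for the same relative spread. PFOS 2 had the fewest reads, at 33.2 M, so its low values do not by themselves place it near a group. Median SDs per gene on the log2 scale were 0.0723 in control, 0.0885 in PFOA and 0.109 in PFOS.

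The first comparison asked which genes PFOA, a long-chain perfluorinated carboxylic acid, changed in maturing dendritic cells. TSC22D3, FKBP5, CYP19A1 and ANGPTL4 were among the genes higher with PFOA, while the lectin CD209, the chemokine CCL13 and the matrix enzymes MMP12 and MMP9 were lower. TSC22D3, a leucine zipper protein of leukocytes, rose from 13.5 ± 1.5 to 88.7 ± 4.16 CPM. CD209, a C-type lectin of dendritic cells also known as DC-SIGN, fell from 106 ± 14.4 to 34.0 ± 4.78. In all, 830 of 13932 tested genes were called by limma, 439 higher and 391 lower. Of these, 392 of the higher and 370 of the lower genes were protein coding. The median absolute log2 fold change of called genes was 0.42, and 47 rose and 23 fell at least 2-fold. In each of the 830 called genes the PFOA and control libraries did not overlap. That held for 4894 of all tested genes, or 35.1%, where chance gives 10%. The count moved with single libraries: it was 255 without control 1, 270 without control 2, 354 without control 3, 317 without PFOA 1, 324 without PFOA 2, 394 without PFOA 3 and 1859 without PFOS 1. It was 374 without a filter, 2043 with array weights, 1852 in a fit of the 6 libraries compared and 1715 with DESeq2.

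The largest rises included genes of very different function. TSC22D3 (ENSG00000157514, chromosome X 107713221 to 107777342) had a log2 fold change of 2.63 (SE 0.09, limma adjusted p = 8.85e-07). CYP19A1 (ENSG00000137869, chromosome 15 51208057 to 51338610), the aromatase that makes oestrogens, went from 30.7 ± 1.75 to 196 ± 18.8 CPM, a change of 2.64 (SE 0.22, limma adjusted p = 2.42e-04). FKBP5 (ENSG00000096060, chromosome 6 35573585 to 35728583), a co-chaperone of steroid hormone receptors, went from 114 ± 11.7 to 496 ± 67.3, a change of 2.10 (SE 0.16, limma adjusted p = 1.29e-04). ANGPTL4 (ENSG00000167772, chromosome 19 8363289 to 8374373), a secreted inhibitor of lipoprotein lipase, went from 2.16 ± 0.616 to 18.5 ± 2.51, a change of 2.64 (SE 0.31, limma adjusted p = 0.00157). FABP4 (ENSG00000170323, chromosome 8 81478419 to 81483263), a fatty acid carrier, went from 17.5 ± 11.6 to 98.9 ± 8.64, a change of 2.66 (SE 0.64, limma adjusted p = 0.0425). NEBL rose by 2.55, and GPC1, a cell surface proteoglycan, by 1.86. ADPRHL1 rose by 2.15, THBS1 (thrombospondin) by 2.13 and AREG (amphiregulin, a ligand of the EGF receptor) by 1.80. FABP4 and ADPRHL1 lost their calls without any of control 1, 2 and 3, PFOA 1, 2 and 3 or PFOS 3, with limma adjusted p up to 0.150 and 0.145. THBS1 lost its call without any control or PFOA library, with adjusted p up to 0.112 in limma. AREG lost its call without control 1, control 2, PFOA 1 or PFOA 2, with adjusted p up to 0.0678 in limma.

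The largest falls held secreted matrix enzymes and surface molecules of myeloid cells. MMP12 (ENSG00000262406, chromosome 11 102862736 to 102875034), macrophage elastase, went from 78.9 ± 6.16 to 19.8 ± 6.69 CPM, a log2 fold change of -1.99 (SE 0.21, limma adjusted p = 8.65e-04). MMP9, gelatinase B, went from 1312 ± 102 to 453 ± 173, a change of -1.60 (SE 0.27, limma adjusted p = 0.00992). CD209 (ENSG00000090659, chromosome 19 7739994 to 7747564) changed by -1.61 (SE 0.14, limma adjusted p = 2.64e-04). CCL13, a chemokine for monocytes and eosinophils, went from 62.1 ± 3.98 to 22.9 ± 2.68, a change of -1.40 (SE 0.09, limma adjusted p = 7.78e-05). VCAM1, an adhesion molecule, fell by 1.83, and JAML, a junctional adhesion molecule of leukocytes, by 1.61. MPEG1, the pore-forming perforin-2 of phagocytes, fell by 1.57. HSD11B1, the enzyme that regenerates cortisol from cortisone, fell by 1.56. ADAM19 fell by 1.52 and TIFAB by 1.51 on the log2 scale. VCAM1 lost its call without control 1, control 2, PFOA 1 or PFOA 2, with limma adjusted p up to 0.0758. MMP9 lost it without control 1 or PFOA 2, with limma adjusted p up to 0.0525.

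**Figure D1:**
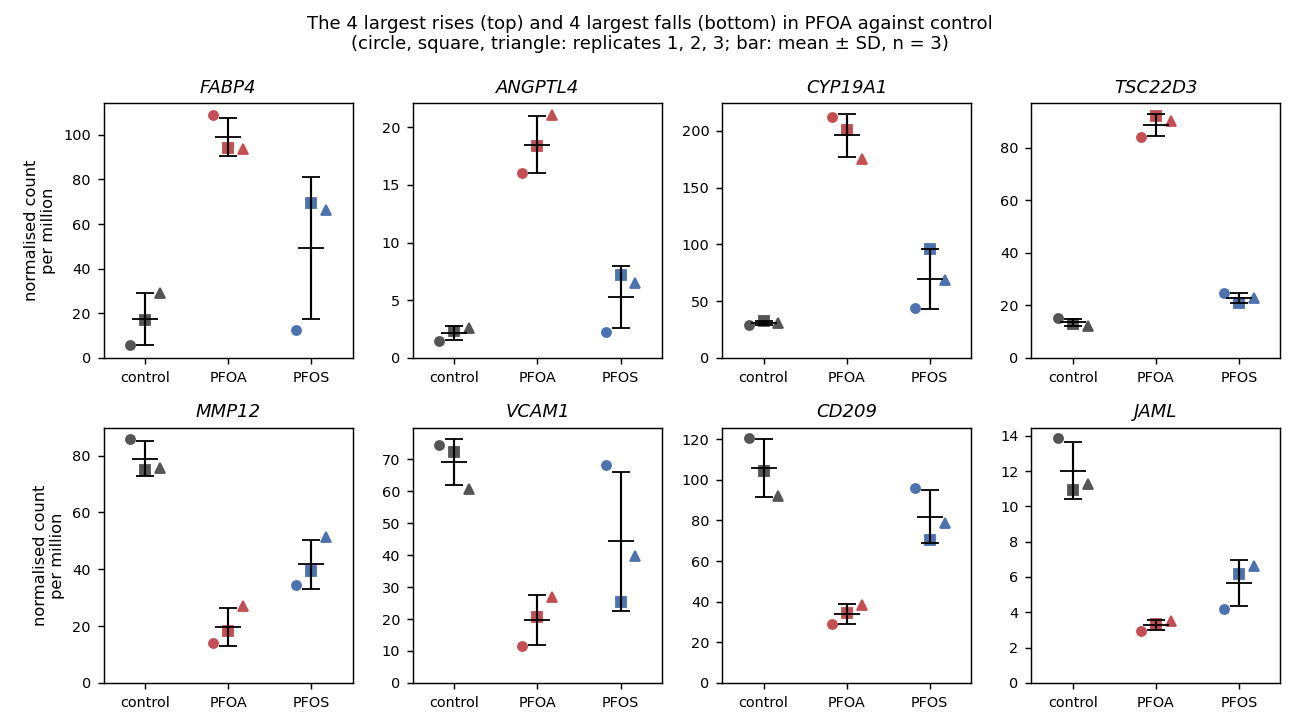
Normalised CPM of the 4 largest rises (top) and 4 largest falls (bottom) in PFOA against control, with 1 point per library and the mean ± SD (n = 3) for control, PFOA and PFOS. TSC22D3 averaged 13.5 in control, 88.7 with PFOA and 22.8 with PFOS, and CD209 averaged 106, 34.0 and 81.7.

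The lists of PPAR targets, integrated stress response, NRF2 and chaperones were higher with PFOA. Of 34 measured PPAR targets and fatty acid oxidation genes, 8 rose, 0 fell and 26 were not called, with 11 up and 0 down adjusted over the list alone. PDK4, the kinase that slows pyruvate oxidation, went from 0.291 ± 0.130 to 3.49 ± 0.386 CPM. PLIN2, a lipid droplet coat protein, went from 179 ± 61.0 to 590 ± 75.2, and ACSL1, which activates fatty acids, from 414 ± 10.9 to 713 ± 66.0. CPT1A, which carries fatty acids into mitochondria, rose by 0.40 (limma adjusted p = 0.0124), a call lost without control 1, control 2 or PFOA 1, with limma adjusted p up to 0.0617. The PPAR list had a median log2 fold change of 0.13 (camera adjusted p = 3.09e-04, and adjusted p = 0.271 with an estimated correlation). Of 28 integrated stress response genes, 6 rose and 0 fell, with 15 up and 1 down adjusted over the list alone. STC2 rose by 0.84, the cytokine GDF15 by 0.87 and the transcription factor CEBPB by 0.63. That list's median was 0.27 (camera adjusted p = 2.71e-09, and adjusted p = 0.271 with an estimated correlation). Of 29 NRF2 antioxidant genes, 2 rose, with 5 up adjusted over the list alone and a median of 0.28 (camera adjusted p = 9.66e-05, and adjusted p = 0.745 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 0.69, a call lost without control 1 or control 2, with limma adjusted p up to 0.0673. HMOX1, another NRF2 target, was not called, at 146 ± 23.2 and 166 ± 52.6 CPM. Of 20 genes of the endoplasmic reticulum chaperone list, 4 rose, with 5 up adjusted over the list alone. The list also holds other stress genes of that compartment, and its 4 called genes were HERPUD1, ERN1, XBP1 and the chaperone DNAJB9. Its median was 0.12 (camera adjusted p = 9.14e-04, and adjusted p = 0.778 with an estimated correlation). HERPUD1 rose by 0.67, a call lost without control 1, control 2, PFOA 1 or PFOA 2, with limma adjusted p up to 0.0885. ERN1, DNAJB9 and XBP1 lost theirs in 5, 6 and 6 of the 9 fits without 1 library, with limma adjusted p up to 0.0923, 0.146 and 0.141. DDIT3, the factor CHOP, was not called, at 27.4 ± 2.16 and 31.7 ± 1.87.

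Lists of the IL-4 response and of MHC class II were lower with PFOA. Of 17 IL-4 and STAT6 response genes, 4 fell, 0 rose and 13 were not called, with 1 up and 10 down adjusted over the list alone. Those 4 were CD209, CCL13, CLEC10A, a galactose-binding lectin that fell by 1.24, and CTSC, a lysosomal protease that fell by 0.46. The list's median log2 fold change was -0.41 (camera adjusted p = 1.75e-05, and adjusted p = 0.25 with an estimated correlation). Of 13 MHC class II genes, 5 fell and 0 rose, with 6 down adjusted over the list alone. The median was -0.26 (camera adjusted p = 2.28e-04, and adjusted p = 0.25 with an estimated correlation). CD74, the invariant chain of MHC class II, went from 534 ± 29 to 393 ± 16.4 CPM, a change of -0.44 (SE 0.06, limma adjusted p = 0.00469). HLA-DRA was low in all groups and went from 3.46 ± 0.561 to 2.13 ± 0.114, and CIITA, the class II transactivator, went from 2.85 ± 0.425 to 1.67 ± 0.329. HLA genes can share reads, so their values are uncertain. HLA-DRA lost its call without any of control 1, 2 and 3, PFOA 1, 2 and 3 or PFOS 3, with limma adjusted p up to 0.132. CIITA lost it without control 1, 2 or 3, PFOA 1 or PFOA 3, with limma adjusted p up to 0.0985. In the 18 MHC class I genes limma called 0 and camera gave an adjusted p of 0.504.

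The maturation list moved in both directions. Of 25 measured dendritic cell maturation genes, 1 rose, 4 fell and 20 were not called, with 2 up and 5 down adjusted over the list alone. FSCN1, the actin bundler fascin of mature dendritic cells, went from 453 ± 28.2 to 329 ± 16.2 CPM (limma adjusted p = 0.00495). MARCKSL1, an actin-associated substrate of protein kinase C, fell by 0.77 and IL15, a cytokine that sustains lymphocytes, rose by 0.53. CD40, the receptor for T cell help, went from 109 ± 8.51 to 84.0 ± 2.60 (limma adjusted p = 0.0212), a call lost without control 1, control 2, PFOA 1, PFOA 2 or PFOA 3, with limma adjusted p up to 0.0818. The costimulatory genes CD80, CD83 and CD86 were not called. Their log2 fold changes had 95% intervals of -0.82 to 0.83 for CD80, -0.44 to 0.73 for CD83 and -0.67 to 0.13 for CD86. CCR7, the lymph node homing receptor, varied widely in control at 5.73 ± 5.12 CPM against 1.58 ± 0.385 with PFOA, and was not called. The list's median was -0.27 (camera adjusted p = 0.0243, and adjusted p = 0.778 with an estimated correlation), and its call was lost without control 1, with a camera adjusted p of 0.167.

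The cytokine and migration lists did not pass camera in PFOA against control, while single genes of them were called. CCL20, a chemokine for immature dendritic cells, was the 1 called gene of 29 inflammatory cytokines and chemokines, going from 12.7 ± 1.09 to 41 ± 1.09 CPM (5 up and 3 down adjusted over the list alone, camera adjusted p = 0.287). TNF at 472 ± 55.8 and 429 ± 86.5 and IL1B at 896 ± 21.9 and 1099 ± 109 were not called. CXCL8, a neutrophil chemokine, averaged 428 ± 72.9 and 943 ± 295 and was not called either, with a limma adjusted p of 0.0963. Of 27 migration, adhesion and matrix genes, 3 rose and 5 fell (4 up and 9 down adjusted over the list alone, camera adjusted p = 0.167). F3, tissue factor, went from 238 ± 21.9 to 422 ± 17.4, and the integrin ITGA4 from 120 ± 2.48 to 94.6 ± 1.99. Of 19 pattern recognition genes, TLR2 rose by 0.63 and TLR8 fell by 1.39 (4 up and 2 down adjusted over the list alone, camera adjusted p = 0.287). Of 27 NF-kB genes, 1 rose and 2 fell (3 up and 3 down adjusted over the list alone, camera adjusted p = 0.438), among them NFKBIE, an NF-kB inhibitor that fell by 0.39.

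**Figure D2:**
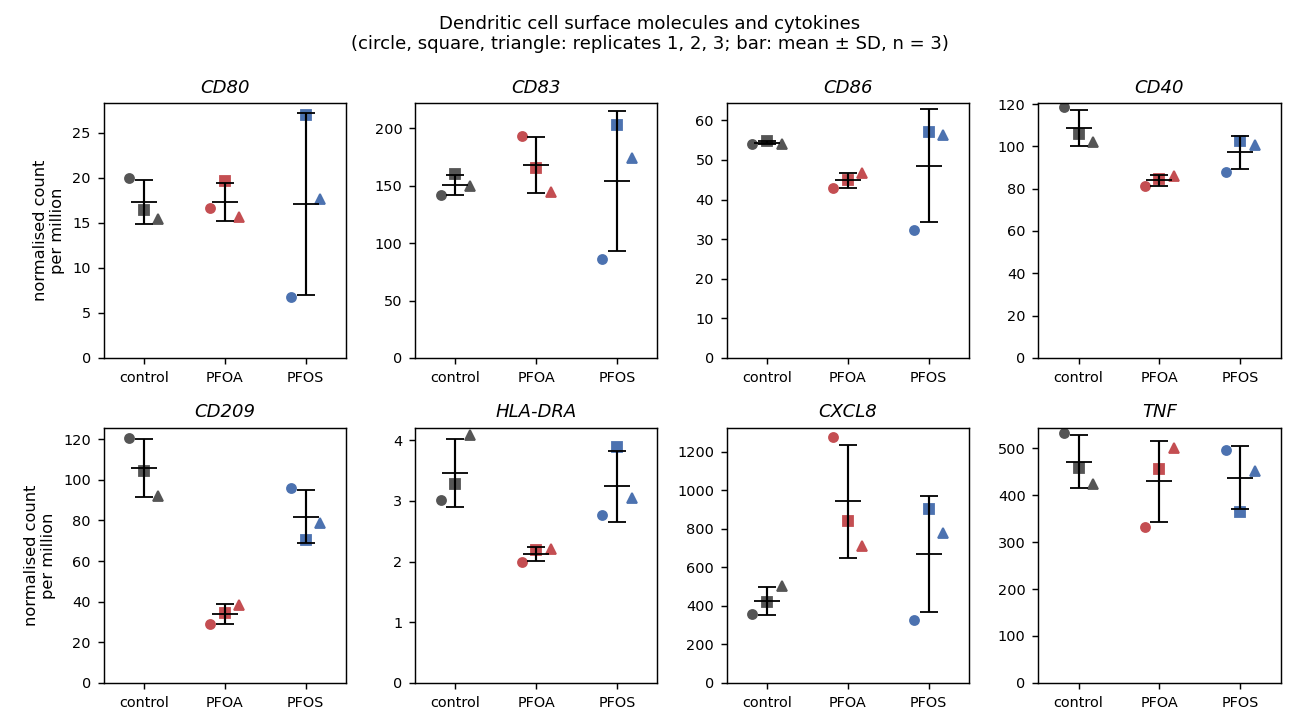
Normalised CPM of 8 dendritic cell surface molecules and cytokines, with 1 point per library and the mean ± SD (n = 3) for control, PFOA and PFOS. CD80 averaged 17.3, 17.3 and 17.1 in the 3 groups, while CD40 averaged 109, 84.0 and 97.1.

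Several lists passed camera in PFOA against control by small shifts with 1 or 2 called members or none. The median log2 fold change was 0.17 over 25 p53 and apoptosis genes (camera adjusted p = 0.00578, and adjusted p = 0.25 with an estimated correlation). MCL1, a survival factor, rose by 0.50 and the p53 target DDB2 fell, with the same counts adjusted over the list alone. DDB2 lost its call without control 1, 2 or 3, PFOA 1 or PFOA 3, with limma adjusted p up to 0.0765. The median was 0.18 over 40 interferon-stimulated genes, where 1 gene rose and 0 did adjusted over the list alone (camera adjusted p = 0.0173, and adjusted p = 0.842 with an estimated correlation). The interferon call was lost without control 3, PFOA 1 or PFOA 2, with camera adjusted p of 0.229, 0.206 and 0.0667. The median was -0.12 over 36 ribosomal protein genes (camera adjusted p = 3.09e-04, and adjusted p = 0.778 with an estimated correlation). It was -0.10 over 30 nuclear genes of oxidative phosphorylation (camera adjusted p = 3.09e-04, and adjusted p = 0.778 with an estimated correlation). Limma called 0 members of these last lists, both over all genes and adjusted over the list alone. Of 29 glycolysis and hypoxia genes 1 fell and 0 did adjusted over the list alone, with a negative median (camera adjusted p = 0.00699, and adjusted p = 0.778 with an estimated correlation). Of 30 lists, camera called 6 up and 7 down, fry called 5, and with an estimated correlation camera called 0, with 5 at an unadjusted p under 0.05.

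Other lists did not pass camera in PFOA against control. They were cholesterol synthesis with 24 genes, LXR targets with 18, heat shock proteins with 16, metallothioneins with 7, xenobiotic receptor targets with 8, calcium and NFAT response with 22, cell cycle with 32, mitochondrial genome transcripts with 13, replication-dependent histones with 7 and lysosome with 24. The camera adjusted p ran from 0.0582 for cholesterol synthesis to 0.889 for xenobiotic receptor targets. Over all genes, 1 LXR target rose, 2 heat shock genes rose, 2 metallothionein genes rose and 1 fell, and 1 lysosome gene rose and 3 fell. Adjusted over the list alone, these were 1 up, 2 up, 3 up with 1 down, and 2 up with 5 down. In the other 6 lists limma called 0 genes, both over all genes and adjusted over the list alone. HMGCS1 of cholesterol synthesis was not called, with a log2 fold change of -0.25. MT2A, a metal-binding metallothionein, rose from 46.2 ± 7.11 to 93.0 ± 7.42 CPM, though it can share reads with its pseudogene and paralogs. MAP1LC3B, an autophagosome protein, rose by 0.54.

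Markers of other cell states were also measured in the PFOA libraries. Of 12 markers of conventional and plasmacytoid dendritic cells, 2 rose and 2 fell, with 2 up and 9 down adjusted over the list alone. The median log2 fold change was -0.35 (camera adjusted p = 0.0173, and adjusted p = 0.729 with an estimated correlation). FLT3, the receptor for a dendritic cell growth factor, rose from 1.86 ± 0.189 to 6.37 ± 0.388 CPM, while CLEC10A went from 10.4 ± 0.124 to 3.94 ± 1.06. Of 13 monocyte and macrophage markers, 3 rose and 2 fell (3 up and 4 down adjusted over the list alone, camera adjusted p = 0.889). The complement gene C1QA rose by 0.91, and CD14 was not called, with a log2 fold change of 0.27. In the 5 neutrophil markers limma called 0, and camera gave an adjusted p of 0.504. Markers of lymphocytes, of epithelium and fibroblasts and of erythroid cells had 2, 1 and 0 measured genes and were not tested. Among them GNLY, granulysin of cytotoxic lymphocytes, rose from 1.97 ± 0.129 to 7.39 ± 0.579 CPM.

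The second comparison asked the same of PFOS, a perfluorinated sulfonic acid. 3 genes were higher and 1 lower with PFOS by limma, and each of the 4 was also called in the same direction with PFOA. CD300A, an inhibitory receptor of leukocytes, rose from 28.1 ± 1.66 to 46.8 ± 4.71 CPM, a log2 fold change of 0.71 (SE 0.08, limma adjusted p = 0.0370). TSC22D3 rose from 13.5 ± 1.5 to 22.8 ± 1.9, a change of 0.71 (SE 0.09, limma adjusted p = 0.0383). PIM1, a survival kinase, rose from 45.8 ± 1.86 to 66.1 ± 3.62, a change of 0.52 (SE 0.06, limma adjusted p = 0.0370). EHF, an ETS transcription factor, went from 4.68 ± 0.404 to 2.30 ± 0.178, a change of -0.78 (SE 0.09, limma adjusted p = 0.0370). EHF lay below the level of the naming rule and was chosen after its values were seen. At an unadjusted p under 0.05 limma had 731 genes and edgeR 781, while adjusted calls were 2 with edgeR and 74 with DESeq2. In 1490 tested genes, or 10.7%, the PFOS and control libraries did not overlap, where chance gives 10%. The count of 4 became 138 without PFOS 1, and it was 0 without control 1, 2 or 3, PFOA 1, 2 or 3 or PFOS 3. It was also 0 without a filter and in a fit of the 6 libraries compared, 1 without a variance trend and 1025 with array weights. With the replicate number as a block, which may pair control and PFOS libraries, limma called 0 genes, with 640 at an unadjusted p under 0.05. CD300A and EHF lost their calls without any of these 7 libraries or PFOS 2, with limma adjusted p up to 0.237 for each. TSC22D3 and PIM1 lost theirs without any of the 7, with limma adjusted p up to 0.341 and 0.237.

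Gene lists shifted with PFOS by small amounts, and limma called 0 of their members over all genes. The integrated stress response, NRF2, PPAR, chaperone and LXR lists were higher: integrated stress response with a median log2 fold change of 0.09 and 1 gene up adjusted over the list alone (camera adjusted p = 1.69e-05, and adjusted p = 0.598 with an estimated correlation), and NRF2 antioxidant genes with 0.15 (camera adjusted p = 5.65e-04, and adjusted p = 0.747 with an estimated correlation). PPAR targets had a median of 0.06 (camera adjusted p = 0.00363, and adjusted p = 0.598 with an estimated correlation). Chaperones had 0.05 (camera adjusted p = 0.00476, and adjusted p = 0.747 with an estimated correlation). LXR targets and fatty acid synthesis genes had a median of 0.03 and 3 genes up adjusted over the list alone (camera adjusted p = 0.0210, and adjusted p = 0.747 with an estimated correlation). The transporter ABCA1 averaged 83.5 ± 5.47 CPM in control and 119 ± 6.39 with PFOS, and was not called over all genes. GDF15 averaged 33.7 ± 1.84 and 55.5 ± 6.31 and was not called, with a limma adjusted p of 0.0942. The PPAR call was lost without PFOS 3 (camera adjusted p = 0.0668). The chaperone call was lost without control 1 or PFOS 3 (camera adjusted p = 0.256 and 0.171). The LXR call was lost without control 2, control 3 or PFOS 1 (camera adjusted p = 0.0505, 0.196 and 0.629), and with the replicate block in the control and PFOS libraries alone (camera adjusted p = 0.0822).

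Lists of maturation, IL-4 response and MHC class II were lower with PFOS. The median log2 fold change was -0.20 over dendritic cell maturation genes (camera adjusted p = 4.02e-04, and adjusted p = 0.735 with an estimated correlation). It was -0.23 over IL-4 and STAT6 response genes, with 3 down adjusted over the list alone (camera adjusted p = 5.65e-04, and adjusted p = 0.598 with an estimated correlation). It was -0.08 over MHC class II genes (camera adjusted p = 0.00253, and adjusted p = 0.598 with an estimated correlation) and -0.19 over markers of conventional and plasmacytoid dendritic cells (camera adjusted p = 0.0245, and adjusted p = 0.735 with an estimated correlation). CCL13 averaged 62.1 ± 3.98 CPM in control and 39.7 ± 3.10 with PFOS, and was not called, with a limma adjusted p of 0.0688. CD80 averaged 17.3 ± 2.40 and 17.1 ± 10.1, and CD86 54.3 ± 0.380 and 48.6 ± 14.2, with neither called. Without PFOS 1 the camera adjusted p was 0.573 for maturation, 0.142 for the IL-4 response and 0.573 for the dendritic cell markers. Without control 1 it was 0.0580 for MHC class II and 0.231 for the dendritic cell markers, and without control 2 it was 0.0836 for these markers.

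Further lists were lower with PFOS by camera. Oxidative phosphorylation had a median of -0.07 (camera adjusted p = 5.65e-04, and adjusted p = 0.747 with an estimated correlation), ribosomal proteins -0.07 (camera adjusted p = 0.00253, and adjusted p = 0.767 with an estimated correlation) and glycolysis -0.08 (camera adjusted p = 0.00313, and adjusted p = 0.747 with an estimated correlation). Cholesterol synthesis had -0.14 (camera adjusted p = 0.00476, and adjusted p = 0.767 with an estimated correlation), NF-kB genes -0.05 (camera adjusted p = 0.00682, and adjusted p = 0.747 with an estimated correlation) and interferon-stimulated genes -0.06 (camera adjusted p = 0.0301, and adjusted p = 0.891 with an estimated correlation). In these lists limma called 0 genes adjusted over the list alone. Leaving out PFOS 1 gave camera adjusted p of 0.0671 for oxidative phosphorylation, 0.269 for glycolysis, 0.573 for NF-kB and 0.0671 for interferon genes, and the direction turned to higher for NF-kB and interferon genes. Without PFOS 2 the ribosomal and cholesterol lists turned to higher, with camera adjusted p of 0.826 and 0.922. Without control 1 the values were 0.260 for NF-kB, 0.575 for interferon genes and 0.349 for cholesterol, and interferon genes had 0.0505 without control 2 and 0.0986 without PFOS 3. With the replicate block in the control and PFOS libraries alone the interferon call was lost too (camera adjusted p = 0.0618), and with the block in all 9 libraries metallothioneins were called lower (camera adjusted p = 0.0485). In all, camera called 5 lists up and 10 down of 30, fry called 0, and camera with an estimated correlation called 0, with 2 at an unadjusted p under 0.05. The median and the camera direction differed in sign for cell cycle and for migration genes, which were not called.

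The third comparison set both compounds side by side. They differ in the acid group, a carboxylate in PFOA and a sulfonate in PFOS, and in the length of the fluorinated chain, and were given at the same mass dose of 10 µg/mL, so that the molar doses differed. Limma told some genes apart between the compounds, TSC22D3, FKBP5 and CD209 among them. TSC22D3 averaged 88.7 CPM with PFOA and 22.8 with PFOS, a log2 difference of -1.92 (95% interval -2.11 to -1.73, limma adjusted p = 1.78e-05). FKBP5 averaged 496 and 139, a difference of -1.85 (95% interval -2.20 to -1.49, limma adjusted p = 0.00125). CD209 averaged 34.0 with PFOA and 81.7 with PFOS, a difference of 1.24 (95% interval 0.93 to 1.55, limma adjusted p = 0.00659), a call lost without PFOA 2, with a limma adjusted p of 0.0504. Limma called 77 genes, 24 higher and 53 lower with PFOS, and 1243 had an unadjusted p under 0.05. Of the 77, 2 were at least 2-fold higher and 11 at least 2-fold lower. In the 77 called genes the PFOA and PFOS libraries did not overlap, as in 1779 of all tested genes, or 12.8%, where chance gives 10%. Of the 77, 76 were also called in PFOA against control, and in 71 of these the PFOS mean lay between control and PFOA. Both counts come from comparisons that share the PFOA libraries, so chance values of these raise them. The count was 51 without control 2, 48 without PFOA 1, 14 without PFOA 2, 36 without PFOA 3, 174 without PFOS 1 and 35 without PFOS 3. It was 40 without a filter, 25 in a fit of the 6 libraries compared, 635 with array weights and 256 with DESeq2.

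Other genes that were lower with PFOS than with PFOA came from several groups. Of the PPAR list, PDK4 differed by -1.43, ACSL1 by -0.51 and ANGPTL4 by -1.73, giving 3 down and 0 up, with 6 down adjusted over the list alone. That list's median was -0.05 (camera adjusted p = 5.54e-04, and adjusted p = 0.270 with an estimated correlation). PLIN2 was not called, with a difference of -0.91 and a 95% interval of -1.51 to -0.31, and FABP4 was not called, with an interval of -2.75 to 0.13. CYP19A1 differed by -1.55, GPC1 by -1.17, and CCL20 averaged 18.4 ± 5.30 against 41 ± 1.09 CPM. FLT3 differed by -1.08, GNLY by -1.09 and MT2A by -1.06. TMIGD3, whose gene overlaps ADORA3, differed by -1.02, a value that is uncertain for that reason. F3 differed by -0.66 and TLR2 by -0.42. STC2 differed by -0.54, the 1 called gene of the integrated stress response (0 up and 4 down adjusted over the list alone), whose median was -0.16 (camera adjusted p = 6.41e-08, and adjusted p = 0.299 with an estimated correlation). TSC22D3, FKBP5, PDK4, FLT3 and TMIGD3 kept their calls in all 9 fits that left out 1 library. ANGPTL4 lost its call without any library but PFOS 1 and PFOS 2 (limma adjusted p up to 0.202). CYP19A1 and MT2A lost theirs without PFOA 1, 2 or 3 or PFOS 3 (limma adjusted p up to 0.100 and 0.0726), and GPC1 and CCL20 without control 2 or PFOA 1, 2 or 3 (up to 0.108 for each). ACSL1 lost its call without PFOA 2, PFOA 3 or PFOS 3 (limma adjusted p up to 0.0841). GNLY and F3 lost theirs without PFOA 2 (limma adjusted p = 0.0622 and 0.0504). STC2 lost it without PFOA 2, PFOA 3, PFOS 2 or PFOS 3 (limma adjusted p up to 0.0992), and TLR2 without these or control 2 (up to 0.108).

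Other genes were higher with PFOS than with PFOA. CCL13 averaged 22.9 CPM with PFOA and 39.7 with PFOS, a log2 difference of 0.77. TIFAB differed by 0.95, MPEG1 by 0.76 and TLR8, an endosomal RNA sensor, by 0.78. TGFA, a growth factor, differed by 0.71 and IGSF6, an immunoglobulin superfamily receptor, by 0.70. CYBB, the catalytic subunit of the phagocyte NADPH oxidase, differed by 0.67 and VASH1 by 0.66. MLXIPL, the glucose-sensing factor ChREBP, was the 1 of the 77 that was not called in PFOA against control, and averaged 17.3 ± 2.77 in control, 11.2 ± 2.51 with PFOA and 21 ± 0.910 with PFOS. Of 17 IL-4 and STAT6 response genes, CD209 and CCL13 were higher and 0 lower, with 5 up adjusted over the list alone and a median of 0.19 (camera adjusted p = 1.88e-05, and adjusted p = 0.214 with an estimated correlation). The 13 MHC class II genes had a median of 0.15, with 0 called by limma over all genes and 3 up adjusted over the list alone (camera adjusted p = 9.51e-04, and adjusted p = 0.270 with an estimated correlation). TGFA and IGSF6 kept their calls in all 9 fits. CCL13 and VASH1 lost theirs without PFOA 2 (limma adjusted p = 0.0546 and 0.0523). TIFAB and CYBB lost theirs without PFOA 2 or PFOS 3 (limma adjusted p up to 0.0703 and 0.0841), and MPEG1 without these or PFOA 3 (up to 0.103). TLR8 lost its call without control 2, PFOA 1, 2 or 3, PFOS 2 or PFOS 3 (limma adjusted p up to 0.129). MLXIPL lost it without any library but PFOS 1 (up to 0.126).

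The maturation list as a whole did not pass camera between the compounds. The 25 maturation genes had a median difference of -0.05 and a mean of 0.02, opposite in sign, with limma calling 0 over all genes and 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.719). The 95% interval of the log2 difference was -1.02 to 0.63 for CD80, -0.79 to 0.38 for CD83 and -0.33 to 0.47 for CD86. It was 0.04 to 0.37 for CD40, and CCR7 had a difference of 0.19 (SE 0.43), with neither called. For the cytokine TNF it was -0.33 to 0.40, and for CXCL8 -1.36 to 0.21. All 40 interferon-stimulated genes were lower with PFOS than with PFOA in their group means, with a median of -0.24 and 0 called by limma over all genes or adjusted over the list alone (camera adjusted p = 6.41e-08, and adjusted p = 0.650 with an estimated correlation). The 7 replication-dependent histone genes, a list for RNA quality, were also all lower, with a median of -0.254, and were not called (camera adjusted p = 0.0565). Against control they were all higher with PFOA, with a median of 0.247, and were not called either (camera adjusted p = 0.240).

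Further lists differed between the compounds by camera. LXR targets and fatty acid synthesis genes were higher with PFOS, with a median of 0.20 and 3 up and 1 down adjusted over the list alone (camera adjusted p = 8.92e-04, and adjusted p = 0.612 with an estimated correlation). ABCA1 of that list had a difference of 0.42 with a 95% interval of 0.19 to 0.65 and was not called over all genes. Migration genes had a median of 0.10 with 1 up and 2 down, and 7 up and 3 down adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.650 with an estimated correlation). Lower with PFOS were p53 genes at -0.10 (camera adjusted p = 9.51e-04, and adjusted p = 0.214 with an estimated correlation) and heat shock genes at -0.08, with 3 down adjusted over the list alone (camera adjusted p = 0.00109, and adjusted p = 0.650 with an estimated correlation). Metallothioneins had -0.19 with MT2A down, and 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.00575, and adjusted p = 0.214 with an estimated correlation). NRF2 genes had -0.14 (camera adjusted p = 0.00233, and adjusted p = 0.650 with an estimated correlation), chaperones -0.07 (camera adjusted p = 0.00860, and adjusted p = 0.650 with an estimated correlation) and MHC class I genes -0.06 (camera adjusted p = 0.0108, and adjusted p = 0.650 with an estimated correlation). These 3 calls were lost without PFOA 1 (camera adjusted p = 0.192, 0.115 and 0.256) or PFOS 1 (camera adjusted p = 0.0771, 0.189 and 0.248). Cytokines had -0.21 with CCL20 down, the same over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.696 with an estimated correlation). That call was lost without PFOA 1, PFOA 2 or PFOS 1 (camera adjusted p = 0.115, 0.0514 and 0.0778), the last with the direction turned. Ribosomal and oxidative phosphorylation genes each had 0.05 (camera adjusted p = 0.0108 and 0.0221, and adjusted p = 0.737 and 0.681 with an estimated correlation). The ribosomal call was lost without PFOA 2, PFOS 1 or PFOS 3 (camera adjusted p = 0.302, 0.0540 and 0.796), the last with the direction turned. The oxidative phosphorylation call was lost without PFOA 2, PFOA 3 or PFOS 3 (camera adjusted p = 0.232, 0.219 and 0.696). The migration call was lost without PFOS 2 or PFOS 3 (camera adjusted p = 0.107 and 0.184). Of 30 lists camera called 6 up and 10 down, fry 3, and camera with an estimated correlation 0, with 5 at an unadjusted p under 0.05. Xenobiotic receptor targets, not called, had a median of 0.01 and a mean of -0.03, opposite in sign.

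Changes under both compounds were compared against what the shared control libraries give. The 4 genes called with both compounds, CD300A, TSC22D3, PIM1 and EHF, compare with a mean of 0.06 (0 to 1) in 100 simulations that kept the PFOA effects and left PFOS unchanged, against the same controls, and with 0.123 for independent lists. Of the 830 genes called with PFOA, 821 had the same sign with PFOS, or 98.9%. The same simulations gave 64.2% with the same sign (62.1 to 66.9). The slope of PFOS on PFOA log2 fold changes over those genes was 0.394, against 0.0780 in the simulations. Across genes, which are not independent replicates, the correlation was 0.80, against 0.50 in 100 simulations with all groups unchanged. The covariance was 0.0240 against 0.0063 in these, a difference of 0.0177. The simulated values already hold the chance spread of the shared controls. With disjoint controls, 91.8% to 96.7% of PFOA-called genes had the same sign with PFOS. The 3 control libraries cannot be split into parts of at least 2, so a smaller part of the excess from the shared controls was not excluded. The simulations drew genes and libraries independently, so they hold no shared deviation of control and PFOS libraries of the same number. Without PFOS 1, 130 genes were called with both compounds. The 4 became 0 without control 1, 2 or 3, PFOA 1, 2 or 3 or PFOS 3, and 0 with the replicate block.

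**Figure D3:**
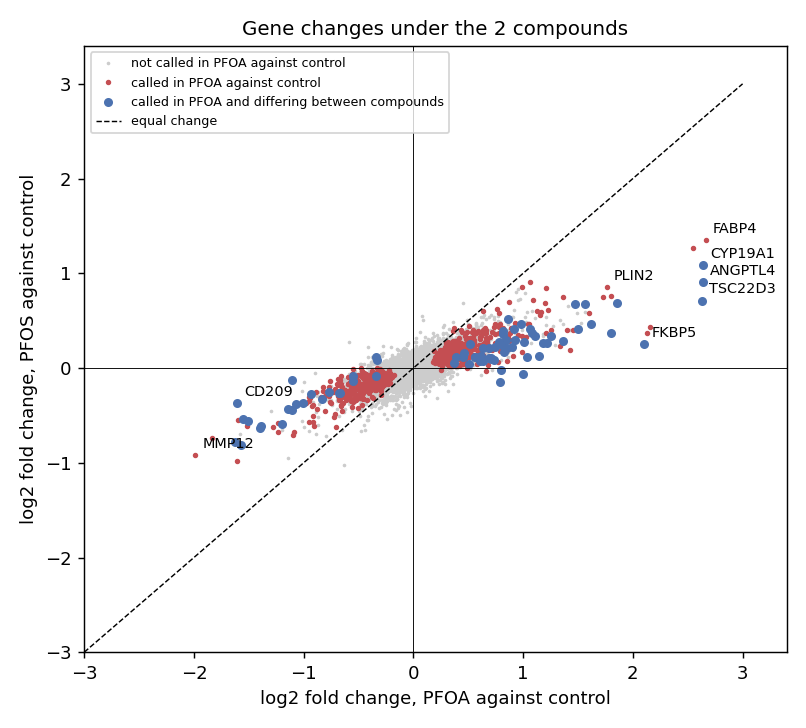
Log2 fold changes of the tested genes in PFOA against control (horizontal) and PFOS against control (vertical), with the 830 genes called with PFOA in red, those of them that also differed between the compounds in blue, and a dashed line of equal change. Of the 830 genes, 821 had the same sign with PFOS.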

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

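The comparison of PFOS 1 with control and PFOA libraries, the comparison of PFOS 2 with PFOA libraries, the thinning of reads and the squared effects were tests chosen after the results had been seen. Differences between the compounds drew attention because the same contrast with control gave different effects by a test of the difference itself. Limma called 77 such genes between PFOS and PFOA. The real split of these 6 libraries gave 77 genes, the highest of the other 9 splits gave 0, and 10 splits are too few for a share under 0.05. That count was 51 without control 2, 48 without PFOA 1, 14 without PFOA 2, 36 without PFOA 3, 174 without PFOS 1 and 35 without PFOS 3.

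Of the 77, 5 were called with PFOA and had the opposite sign with PFOS, where none was called. MT2A, a metallothionein, averaged 46.2 ± 7.11 CPM in control, 93.0 ± 7.42 with PFOA and 44.5 ± 9.76 with PFOS (SD, n = 3), a log2 difference of -1.06 (limma adjusted p = 0.0136). JDP2, a repressor of AP-1 activity, averaged 26.6 ± 1.76, 47.3 ± 5.97 and 26.3 ± 1.40, a difference of -0.82 (limma adjusted p = 0.00659). The metallothionein pseudogene MT2P1 differed by -0.94 (limma adjusted p = 0.0121), and it can share reads with MT2A. TBL2 differed by 0.42 (limma adjusted p = 0.0179) and MYBPH by 0.45 (limma adjusted p = 0.0244). Of these genes, MT2A fell under the naming rule and the 4 others were chosen after their values were seen. JDP2 kept its call in all 9 fits without 1 library. MT2A, MT2P1 and TBL2 lost theirs without PFOA 1, 2 or 3 or PFOS 3 (limma adjusted p up to 0.0726, 0.0634 and 0.105). MYBPH lost its call without any library but PFOA 1 and PFOS 1 (limma adjusted p up to 0.130). In PFOA against control the calls of MT2A, JDP2 and MT2P1 held in all 9 fits. The call of TBL2 there was lost without control 1, control 2, PFOA 1 or PFOA 2 (limma adjusted p up to 0.0707). The call of MYBPH there was lost without control 1, 2 or 3, PFOA 2 or PFOA 3 (limma adjusted p up to 0.0934).

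The 40 interferon-stimulated genes had a median log2 difference of -0.24 between PFOS and PFOA (camera adjusted p = 6.41e-08, and adjusted p = 0.650 with an estimated correlation). The 7 replication-dependent histone genes, a list for RNA quality, had a median of -0.254 there and of 0.247 in PFOA against control (camera adjusted p = 0.0565 and 0.240), so a part of RNA quality in the interferon shift was not excluded. The list of interferon-stimulated genes passed camera as higher with PFOA and lower with PFOS against control (camera adjusted p = 0.0173 and 0.0301, and adjusted p = 0.842 and 0.891 with an estimated correlation). Without PFOS 1 the PFOS direction turned to higher, with a camera adjusted p of 0.0671, and the PFOS call was lost without control 1, control 2 or PFOS 3, with 0.575, 0.0505 and 0.0986. It was also lost with the replicate block in the control and PFOS libraries alone (camera adjusted p = 0.0618). The PFOA call was lost without control 3, PFOA 1 or PFOA 2, with camera adjusted p of 0.229, 0.206 and 0.0667. The range of the PFOS value over all fits that left out 1 library was 3.94e-13 to 0.575.

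Few genes passed in PFOS against control. Without PFOS 1 the count rose from 4 to 138, while it was 4 without PFOS 2 and 0 by limma without any other library (442 to 791 at an unadjusted p under 0.05), so spread added by PFOS 1 may account for part of the low count. Low depth of PFOS 2 as the whole cause is argued against by all libraries thinned to its depth, which left 737 genes called in PFOA against control, though thinning cannot test what more reads in PFOS 2 would give. PFOS 1 lay nearer to the controls than to PFOS 2 and 3 (chi-square per gene 48.8 to 56.0, against 83.8 and 71.8). PFOS 2 lay at 21.9 to 30.7 from the PFOA libraries and at 19.7 from PFOS 3, though its low depth may lower these values. On the second principal component PFOS 1 lay at -14.6 against 6.49 to 8.42 in control. PFOS 2 lay there at 10.6 against -11.5 to -1.79 with PFOA. Wrong labels are argued against by a score where control averages 0 and PFOA 1. Left-out control libraries had at most 0.112 and left-out PFOA libraries at least 0.892. PFOS 1 had 0.262 on the 830 PFOA-called genes and 0.277 to 0.309 on the genes used for the controls. PFOS 2 had at most 0.466 on the genes used for the PFOA libraries. A smaller effect of PFOS than of PFOA may take part beside the spread, since the mean squared effect over all tested genes, from products of changes in disjoint libraries, was -0.00197 with PFOS (-0.0177 to 0.0177 with 1 library left out, the highest without PFOS 1) and 0.0471 with PFOA (0.0424 to 0.0535), while the real split gave 4 genes and the highest of the other 9 splits 2, with 10 splits too few for a share under 0.05.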

How the results depend on the processing

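Settings chosen after the data were seen were edgeR, DESeq2, thinned reads, the GC and length correction, lists with 1 or 2 members and the block in control and PFOS libraries alone. Main counts by limma were 830 genes with PFOA, 4 with PFOS, 77 between compounds and 4 with both. They stayed within 1.5 times under both other pseudocounts, a stricter filter, quantile normalisation, median centring, thinned reads and the GC and length correction. None of these called genes changed sign under any setting. In the same order of 4 counts, other settings gave 374, 0, 40 and 0 without a filter (more genes tested, 1608 for PFOS at an unadjusted p under 0.05), 70, 0, 13 and 0 with a 2-fold threshold, and 1852, 0, 25 and 0 in fits of the 6 libraries compared (625 for PFOS unadjusted). DESeq2 gave 1715, 74, 256 and 71. Array weights gave 2043, 1025, 635 and 644, where PFOS 3 had a weight of 8.36 and the weights stopped short of convergence. PFOS and shared counts were 1 and 1 without a variance trend, and 2 and 2 with edgeR (781 for PFOS unadjusted, against 731 with limma). Fits without 1 library gave 255 to 1859 genes with PFOA, 0 to 138 with PFOS, 14 to 174 between compounds and 0 to 130 with both, lowest without control 1 for PFOA and PFOA 2 between compounds, and highest without PFOS 1. Of named calls, 46 of 87 with PFOA, 0 of 4 with PFOS and 8 of 31 between compounds held in all 9 such fits. Camera called 13, 15 and 16 lists in the 3 comparisons; with an estimated correlation it called 0, 0 and 0, and fry 5, 0 and 3. With lists of 1 or 2 members it called 13, 15 and 17.

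With the replicate number as a block, limma gave 443, 0, 40 and 0 genes (640 for PFOS unadjusted). In the control and PFOS libraries alone, the groups that the numbers may pair, the replicate block gave 0 genes (783 unadjusted). It lost the PFOS calls of interferon genes (camera adjusted p = 0.0618) and LXR targets and fatty acid synthesis (camera adjusted p = 0.0822). The block in all 9 libraries added metallothioneins (camera adjusted p = 0.0485). The block changed no other list call of PFOS against control. In the 2 other comparisons libraries of the same number did not deviate together. Over all groups, 3 of 9 libraries had their highest correlation with a library of their own number.

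List directions that turned had these camera adjusted p. With array weights, for PFOS against control: cytokines 0.00413, cell cycle 3.92e-05, glycolysis 0.531, mitochondrial genome 0.0215, ribosomal proteins 0.0767 and histones 0.0136; between compounds, cytokines 0.809. Without 1 library, lists that turned in PFOS against control ranged from 5.34e-05 (without PFOS 1, turned) to 0.673 for cytokines, 2.33e-05 to 0.573 (without PFOS 1, turned) for NF-kB, 3.94e-13 to 0.575 for interferon genes (0.0671 without PFOS 1, turned) and 1.63e-07 to 0.922 (without PFOS 2, turned) for cholesterol. Cell cycle ranged from 7.04e-07 (without control 1, turned) to 0.97, mitochondrial genome from 0.0382 (without PFOS 1, turned) to 0.791, ribosomal proteins from 4.00e-09 to 0.826 (without PFOS 2, turned) and histones from 5.63e-04 (without PFOS 1, turned) to 0.933. Between compounds the ranges were 3.35e-04 to 0.115 for cytokines (0.0778 without PFOS 1, turned), 0.00505 to 0.696 for cholesterol (0.00686 without PFOS 1, turned) and 3.04e-07 to 0.796 (without PFOS 3, turned) for ribosomal proteins. The cause was not tested.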

Other observations

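The test of the ratio between PPAR and glucocorticoid targets was chosen after the result was seen, as was the correction for GC content and length. The glucocorticoid list used here was written after the 25 leading genes of each comparison had been seen and before any value of its members was examined, and it left out such leading genes. It still held ANGPTL4, named above among the largest rises with PFOA (log2 fold change 2.64), which is also on the PPAR list. Of its 46 measured genes, 12 rose and 2 fell with PFOA, with 14 up and 2 down adjusted over the list alone. TNFAIP3, ANXA1, DDIT4, MT1X and RHOB lost these calls in 3, 4, 5, 5 and 6 of the 9 fits without 1 library. Their limma adjusted p there ran up to 0.0576, 0.0741, 0.0673, 0.102 and 0.0865. The other called genes of the list, which include the examples below, kept their calls in all 9 fits. The examples that follow were chosen after their values were seen. PER1, a clock gene, averaged 28.7 ± 0.608 CPM in control, 68.6 ± 7.84 with PFOA and 35.2 ± 6.60 with PFOS (SD, n = 3). ERRFI1, an inhibitor of EGF receptor signalling, averaged 19.7 ± 1.51, 47.9 ± 12.2 and 26.1 ± 5.27. TPST1, a tyrosine sulfotransferase, averaged 9.81 ± 0.205, 19.3 ± 2.65 and 11.6 ± 0.310. The immune receptor LILRB1 averaged 62.2 ± 14.2, 32.9 ± 3.73 and 51.4 ± 2.74. In PFOS against control limma called 0 of these genes, over all genes or over the list alone, and the median was 0.01 (camera adjusted p = 0.399, with 1 list tested). Between the compounds 5 were lower and 0 higher with PFOS, with a median of -0.11 (camera p = 9.12e-09, and p = 0.0337 with an estimated correlation).

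Several leading PFOA genes are known glucocorticoid targets, among them TSC22D3, FKBP5 and PDK4. As a hypothesis, glucocorticoid receptor activity may take part. The held-out list was higher with PFOA, with a median log2 fold change of 0.12 and a camera p of 7.09e-05, though p = 0.107 with an estimated correlation. Without PPAR list members its median was 0.06, with a camera p of 9.56e-04 (p = 0.149 with an estimated correlation). That median lay below what the prediction for the full list had asked. Of its other risers, CEBPB and DDIT4 are also on the integrated stress response list. MT2A and MT1X are on the metallothionein list and TNFAIP3 is on the NF-kB list. The rise therefore does not set glucocorticoid targets apart from these groups. PPAR activity stays open beside glucocorticoid receptor activity. The fixed PPAR list had a camera p of 6.50e-05, and with an estimated correlation an unadjusted p of 0.0438 (adjusted p = 0.271). Without glucocorticoid targets its camera p was 0.00619 (p = 0.138 with an estimated correlation). PDK4 had been seen when the PPAR prediction was written. Bias from GC content or gene length is argued against, since the held-out list kept a camera p of 3.70e-05 (p = 0.0904 with an estimated correlation, against 0.107 before) and a median of 0.10 after a correction. The real split of control and PFOA libraries gave 830 genes and the highest of the other 9 splits 0, and 10 splits are too few for a share under 0.05.

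Changes with PFOS followed those with PFOA in sign. Chance spread of shared control libraries as the whole cause is argued against by disjoint controls, with PFOA set against 2 control libraries and PFOS against the remaining library: the share of PFOA-called genes with the same sign was 91.8% at the lowest and 96.7% at the highest of the 3 choices. A deviation common to all 3 control libraries would remain in this test. Log2 fold changes correlated with GC content at -0.179 with PFOA and -0.182 with PFOS. The shared sign was not computed again after the GC and length correction. Whether PPAR targets keep a larger share of the PFOA change with PFOS than glucocorticoid targets cannot be told apart from no difference with 6 and 12 genes. The median ratio of PFOS to PFOA changes was 0.404 and 0.239, and a two-sided permutation test with 100000 resamples over genes gave p = 0.0757. PDK4 was counted there as a PPAR target and above as a glucocorticoid target. Without PDK4 the medians were 0.483 and 0.239 and the permutation p = 0.0160, so the result hangs on that gene. These genes were measured in the same libraries and are not independent replicates, so neither p measures the spread between libraries.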
